A study of Xenopus laevis with 64 samples.

How the data were processed

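Hindlimb and tail RNA of Xenopus laevis tadpoles, exposed from NF stage 54 to thyroid hormones or to inhibitors of hormone synthesis, was amplified, labelled with P32 and hybridised to a small cDNA array, per the labels' protocols. The 64 arrays fall into 20 groups, by tissue, time and exposure, with 1 array for each replicate. The groups given T3 or T4 hold 4 arrays each and all others 3. Per the labels, animals of a treatment came from few tanks, and which animals shared a tank is not given in the sources used here, so p-values measure the spread between animals only.

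The deposited values are spot intensities on a linear scale, with background already subtracted: between 19.9 and 50.6% of the measured spots of an array lie below 0. Array medians run from -17.9 to 281. In each of the 7 sets of arrays that share tissue, time and exposure experiment, exactly 1 array holds only whole numbers, and the values of different sets were not brought to 1 scale. The scanner, the background method, the reference array of each scaling and the rule that left spots blank are not given in the sources used here. Blank spots make up 0.739 to 12.4% of an array.

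The array holds 812 spots in 406 neighbouring duplicate pairs, whose 2 spots correlate across pairs with r between 0.893 and 0.986. A gene symbol was available for 237 pairs (230 symbols), none for 169 and several for 0. The platform's older symbols were replaced through their gene identifiers by those of the Xenopus_laevis_v10.1 annotation for 233 pairs. That annotation served for names only, and the endings L and S mark the long and short subgenomes. The noise of each array was taken as 1.4826 times the median size of its negative values, and a pair counts as above background where its mean exceeds 2 such noise SD. Between 22 and 93 pairs of an array were above background (median 48.5). No 2 arrays held identical values.

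Because values at or below 0 have no log, spots were passed through normexp (offset 50) in limma 3.58.1 (R 4.3.3, statmod 1.5.0), put on the log2 scale, quantile normalized within each tissue and averaged over duplicates. This treatment was chosen after the distribution of values was seen and before any contrast was fitted. It acts like an added constant, which shrinks changes of dim probes. Values at background still spread after it, so changes there are not always understated. With PTU at 96 h, pou2f1.S read 1.64, and 0.62 with a floor in place of normexp. A pair was tested where at least 3 arrays of the groups compared were above background. All arrays of a tissue were fitted together by lmFit and eBayes, with 1 coefficient per group, so each SE pools the spread over all its groups. The p-values were adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05. The comparison of the tissues used the control arrays of hindlimb at 24 h and tail at 48 h, normalized together, with the exposure set as a fixed term. Where a called pair was not above background on any array of a group, its fold is given as a lower bound against the dimmest signal above background on each array, written as at least. For pou2f1.S there is no such bound, since its mean with PTU lay below the mean of these dimmest signals on the control arrays. Its group means are given instead. Pairs that were not called, and differences of effects, are given by their fitted log2 values even where a group was below background, and such values rest on the level of the background.

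The procedure was tested on simulated data of the same size, in 20 runs for each arrangement and with 5 pairs changed by each size in a run. The changed pairs were drawn only from bright pairs of the tissue, so the shares and estimates below do not cover dim pairs. For hindlimb at 96 h with PTU, log2 changes of 2 that went both ways were called in 74% of cases and estimated at a median of 1.56. Changes of 1 were called in 27% and estimated at 0.77. Where all changed pairs rose, the estimates were 0.77 and 0.34, and the calls fell to 29% and 4%, while unchanged pairs were estimated at -0.20. The arrangement with changes both ways was added after the result for rises only was seen. For tail with T3 the calls were 76% and 35% for changes both ways, and 42% and 2% for rises only.

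The comparisons, the gene lists and the rule for named genes were fixed before the data were examined. By that rule, up to 12 named genes in each direction with adjusted p under 0.05 are named in a treatment comparison and up to 6 in others. Where fewer than 4 pairs passed, the 3 named genes with the smallest unadjusted p are given as values. Members of a list of thyroid hormone response genes are given throughout, with up to 4 members of any list that passes. Lists with at least 4 tested pairs were tested by cameraPR with an inter-gene correlation of 0.01, or with an estimated one. Alternatives covered the arrays fitted, the scaling, dim and incomplete probes, array weights, the replicate number as a block, each array left out, and the submitters' own selection rule. That rule, per the labels, takes folds of at least 2 with a half-range of at most 1.1 and at least 4 observations; the scale of the half-range is not stated, and log2 was assumed, with values above background only. Other hormone concentrations named in the labels are not analysed here.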

Results

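Gene expression was measured in hindlimb and tail of Xenopus laevis tadpoles, organs that grow and regress under thyroid hormone at metamorphosis. Tadpoles were exposed to T3 (1.92 nM) or T4 (10 nM), or to an inhibitor of the thyroid: PTU (propylthiouracil, 20 mg/L), MMI (methimazole, 100 mg/L) or PER (perchlorate, 4 mg/L). Hindlimbs were taken at 24 h, and with inhibitors also at 96 h, and tails at 48 h, giving 38 hindlimb and 26 tail arrays. Hormone groups held 4 animals and all other groups 3. T3 and T4 each had their own controls, and the inhibitors shared 1 control group per tissue and time. Of the 406 duplicate spot pairs, 93 were above background on at least 3 hindlimb arrays and 79 on at least 3 tail arrays, so the results below concern bright transcripts. The number of arrays limits the precision.

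Gene lists could be matched to the 237 named pairs only, and the 169 pairs without a gene name may hold further members. Of the fixed list of thyroid hormone response genes, 3 were named on the array, thibz.L, fap.L and mmp9.1.S. They were not well above background on any of the 64 arrays, except mmp9.1.S on 1 of 4 tail arrays with T4. No treatment comparison could therefore test them. This concerns the list only: thdl17.L and thdl18.S were not on it, were tested, and are given below where the rule names them. The lists for apoptosis, epidermis, immune, liver and pituitary genes likewise held 0 named pairs above background on at least 3 arrays of either tissue. Lists for matrix, nuclear receptors, chromatin, nervous system, limb patterning, blood, stress and muscle held at most 3, under the 4 needed for a test.

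The clearest contrast lay between the tissues. In controls, 31 of 70 tested pairs differed between tail at 48 h and hindlimb at 24 h, 18 higher and 13 lower in tail (9 arrays each). With arrays centred on bright probes the median change moved from 0.03 to 0.72, so this balance depends on the scaling. Among the 18, pair 250 (1.34) and pair 403 (1.76) differed between exposure sets of the tail. Normalized within tail, pair 250 averaged 10.1 in T3 controls and 14.8 in T4 controls. Pair 403 was above background on 0 of 3 T3 controls and 2 of 3 T4 controls. Of the list for cell cycle and replication, all 4 tested members were lower in tail, and 4 passed when adjusted over the list alone. The cyclin gene ccnd2.L differed by -2.98 on the log2 scale (SE 0.27, adjusted p = 5.63e-08, lower in 9 of 9 tails than the hindlimb mean), and ccnd1.L by -2.35 (SE 0.26). The mitotic kinase gene cdk1.S differed by -1.73 (SE 0.23), and pcna.S, the sliding clamp of DNA replication, by -1.72 (SE 0.21). With bright centring cdk1.S read -0.98 and stayed a call. The list test gave an adjusted p of 0.000132, and an adjusted p of 0.0092 with an estimated correlation.

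Genes of muscle and of glycolysis went both ways. Desmin (des.1.S), an intermediate filament of muscle, was at least 3.40-fold higher in tail (adjusted p = 2.07e-05), and tropomyosin tpm4.S was higher by 1.89 (SE 0.43). The remaining muscle pair tested, myf5.L, named after its value was seen, was lower (-1.17, SE 0.37, adjusted p = 0.0148), and 3 muscle pairs were too few for a list test. The glycolytic genes pkm.S and aldoc.L were at least 3.15-fold and 2.36-fold higher. All 3 pairs for gapdh.S, which also encodes a glycolytic enzyme, were lower in tail, by log2 changes of -2.78, -2.69 and -2.67. Of the 6 tested pairs of the energy list, 3 were thus higher and 3 lower, and 6 passed when adjusted over the list alone, but the list test gave an adjusted p of 0.243. thdl17.L was higher in tail by 2.34 (SE 0.36), and rest.S, a repressor of neuronal genes, was at least 1.54-fold lower (fitted at -1.73, and at -0.98 with bright centring, which stayed a call). ppp3ca.S was higher by 3.67 (SE 1.01), but it was measured on 2 tail and 3 hindlimb arrays only. That call ended with the deposited values as they stand (2.31, adjusted p = 0.119) and without replicate 1 or 3 of the hindlimb inhibitor controls (adjusted p = 0.0615 and 0.0581). Tissue, time and the separately scaled sets of arrays differ together here. Among the tail controls 1 array, replicate 3 of the T4 set, read des.1.S, pkm.S and aldoc.L at hindlimb levels.

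**Figure D1:**
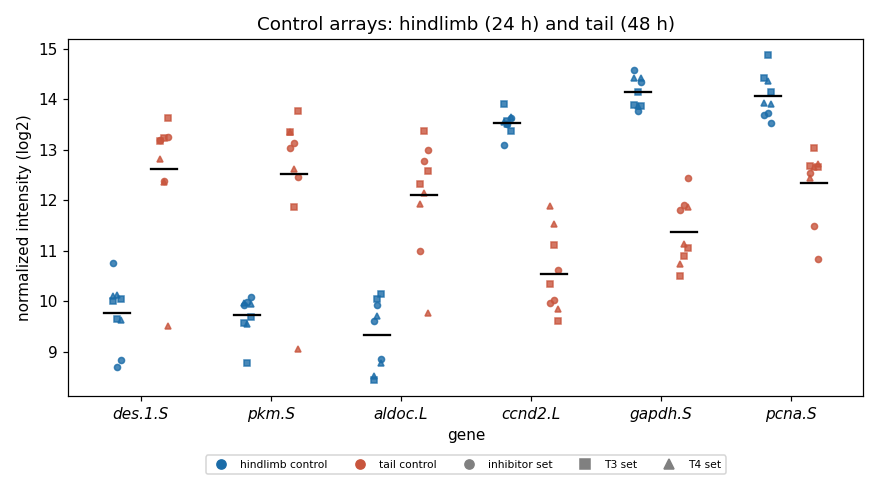
Normalized intensity (log2) of 6 genes on each control array, hindlimb at 24 h in blue and tail at 48 h in red, with bars at the mean of 9 arrays and marker shapes for the exposure set. des.1.S averaged 12.62 in tail against 9.76 in hindlimb, and ccnd2.L 10.54 against 13.53.

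T3 in the tail gave 0 calls among 52 tested pairs in limma, with 6 at an unadjusted p under 0.05 where 2.60 were expected. The smallest p belonged to tuba1, an alpha-tubulin gene, with a log2 change of 1.57 (SE 0.43, adjusted p = 0.0773, higher than the control mean in 4 of 4 animals). The chaperonin subunit gene cct3.S, measured on 3 of the T3 arrays, read 1.30 (SE 0.50) and the beta-tubulin gene tubb4b.L 1.40 (SE 0.55), both with an adjusted p of 0.294. None of the 3 was above background in a control. Being above background is not comparable between these groups. For gapdh.S (pair 402), at means of 10.87 with T3 and 10.88 in controls, 3 of 4 and 0 of 3 arrays were above it. With array weights 6 pairs were called, 4 higher and 2 lower, and 2 were called when only these groups were fitted. Over its alternatives the adjusted p of tuba1 ran from 0.00348 to 0.445, and it passed in 4 of 12. cct3.S read from 0.98 to 2.26.

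T4 in the tail gave 0 calls among 58 pairs, with 4 at an unadjusted p under 0.05. The named genes with the smallest p were des.1.S at 1.24 (SE 0.49), thdl18.S at 1.46 (SE 0.63) and the ribosomal protein gene rpl8.S at -0.49 (SE 0.25), each with an adjusted p of 0.558. Of the 3 controls, replicate 3 lay below background for des.1.S and thdl18.S. Without that replicate, des.1.S read 0.25 and thdl18.S 0.29. Without control replicate 1, des.1.S read 1.82 and passed. With median centring rpl8.S read -0.04.

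In the hindlimb at 24 h, T3 gave 0 calls among 53 pairs and 0 at an unadjusted p under 0.05. rest.S read -0.77 (SE 0.41), ldhb.S 0.16 (SE 0.17) and odc1.L 0.52 (SE 0.63), all with an adjusted p of 0.996. Over the alternatives they ran from -1.19 to -0.60, from 0.09 to 0.31 and from 0.26 to 1.00; the 0.26 came without control replicate 1, the 0.09 without T3 replicate 2, and none passed. T4 gave 0 calls among 44 pairs, with 6 at an unadjusted p under 0.05. The metallothionein gene mt4.L read 2.67 (SE 0.80, adjusted p = 0.112), rest.S 1.18 (SE 0.41, adjusted p = 0.161) and the proteasome subunit gene psma2.L 1.45 (SE 0.68, adjusted p = 0.351). Without control replicate 1, mt4.L and rest.S read 3.47 and 1.61 and passed. Over all alternatives mt4.L passed in 2 of 15 and rest.S in 1 of 16. Without control replicate 2 rest.S read 0.54, and without control replicate 3 psma2.L read 0.36 and mt4.L 1.95. The lists tested in the 4 hormone comparisons did not pass: their adjusted p ran from 0.13 to 0.905. Of all 55 list tests, 6 passed, and 4 with an estimated correlation. In 17 of them the list's median, mean and test did not share a sign, none of them passing.

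T4 carries an outer-ring iodine that T3 lacks, and their effects were set against each other, each against its own control and at different concentrations. The difference of effects gave 0 calls among 57 pairs in hindlimb, with 3 at an unadjusted p under 0.05, and 0 among 69 in tail, with 4. The median half-width of the 95% intervals was 1.17 and 1.29 on the log2 scale, so a 2-fold difference was mostly not detectable. In hindlimb the smallest p belonged to pair 393, at 3.28 (SE 0.96, adjusted p = 0.0615). That pair has no gene name here and was picked after its value was seen. It was above background on 0 of 4 arrays with T4 and on 2 of 3 T4 controls (SD 2.92). At 96 h it was above background on 0 of 3 arrays with PTU and 0 of 3 with PER, so it varied between sets of arrays. Among named genes the smallest p belonged to rest.S at -1.94 (SE 0.58, adjusted p = 0.0615), followed by hbd.S at 1.27 (SE 0.66) and mt4.L at -2.19 (SE 1.17). rest.S passed in 6 of its 23 alternatives, with adjusted p from 0.011 to 0.387, and its values ran from -2.67 to -1.31. hbd.S ran from 0.71 to 2.12 and mt4.L from -3.07 to -1.31. In tail the named genes with the smallest p were tuba1 at 1.90 (SE 0.60, adjusted p = 0.348), cct3.S at 1.67 (SE 0.68) and rpl8.S at 0.76 (SE 0.35). tuba1 passed in 3 of 22 alternatives (adjusted p from 0.00493 to 0.984), among them without T4 control replicate 3, at 2.44. cct3.S ran from 1.33 to 2.84 and passed in 1 of 21, and rpl8.S read 0.09 with the deposited values. Across probe pairs, which are not independent replicates, the changes with T3 and T4 correlated with r = 0.12 in hindlimb (-0.575 over complete probes) and 0.247 in tail. Unchanged groups gave a mean r of -0.00821 and 0.00395 in 1000 simulations, 95% of them from -0.557 to 0.536 and from -0.574 to 0.557, so 0.12 and 0.247 lay inside. Over complete probes, 32 of the 44 pairs in hindlimb, the same simulation, run after that value was seen, gave -0.597 to 0.623, and -0.575 lay inside that range near its end.

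Among inhibitors in the hindlimb at 96 h, PTU gave 4 calls among 47 pairs, all higher. tuba1 was at least 1.57-fold higher (adjusted p = 0.0336, 3 of 3 animals). pou2f1.S, a POU-domain transcription factor gene, averaged 11.24 ± 0.14 with PTU against 9.60 ± 0.26 in controls on the log2 scale (SD, n = 3, adjusted p = 0.0259), with no control above background. That mean with PTU lay below the dimmest signals above background on the controls, on average, so a lower bound on its fold cannot be given. With a floor in place of normexp, pou2f1.S read 0.62 (adjusted p = 0.351). Over their alternatives tuba1 passed in 7 of 12 (adjusted p from 0.0139 to 0.348) and pou2f1.S in 6 of 11 (adjusted p from 0.0068 to 0.351). The other calls have no gene name here: pair 88 was at least 1.65-fold higher and pair 260 was higher by 1.56 (SE 0.43). MMI gave 2 calls among 29 pairs, nkx2-2.S, a homeobox gene, at 1.37 (SE 0.41, adjusted p = 0.036) and pair 260 at 1.44 (SE 0.43). These SEs pool all hindlimb groups and understate the spread of the 3 controls, whose SDs were 1.49 and 1.59. With MMI the SDs were 0.16 and 0.32. Among named genes the next were hmgn3.L at 2.15 (SE 0.80, adjusted p = 0.097) and tpm4.S at 2.74 (SE 1.12, adjusted p = 0.101). nkx2-2.S ran from 0.63, without control replicate 2, to 2.11, without control replicate 3, and passed in 6 of 15 alternatives. hmgn3.L passed in 1 of 14, without control replicate 3. PER gave 1 call among 35 pairs, pair 260 at 1.54 (SE 0.43, adjusted p = 0.0473). With control replicate 2 left out, the 4, 2 and 1 calls fell to 0, 0 and 0, as they did without any single array of the inhibitor concerned, with the deposited values as they stand and with array weights. Without control replicate 3 they were 9, 3 and 5.

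**Figure D2:**
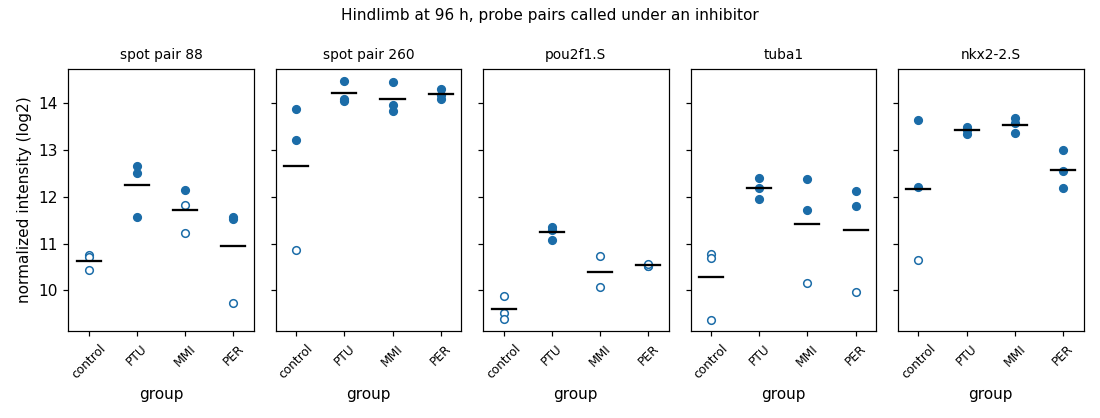
Normalized intensity (log2) on each hindlimb array at 96 h for the 5 probe pairs called with an inhibitor, by group, with bars at group means; filled points are above background and open points are not. For pair 260 and nkx2-2.S, 1 of the 3 controls lies below background, and for pou2f1.S all 3 do.

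With PER at 96 h the cell cycle list lay low relative to the other tested pairs by cameraPR (adjusted p = 0.0161, and an adjusted p of 0.0148 with an estimated correlation). The median change over all tested pairs was 0.22, and of the list only the 2 cyclins were lower than in controls. None of its 4 members passed over all pairs, and 2 passed when adjusted over the list alone. ccnd1.L read -0.81 (SE 0.29) and ccnd2.L -0.59 (SE 0.21), both with an adjusted p of 0.105, pcna.S 0.24 (SE 0.21) and cdk1.S 0.13 (SE 0.49). The list passed in 5 of 9 alternatives. It did not with array weights (adjusted p = 0.1), with bright centring (adjusted p = 0.26), with the deposited values as they stand (adjusted p = 0.311) or with median centring (adjusted p = 0.563), where ccnd1.L read 0.17 and ccnd2.L 0.01. hmgn3.L read 2.15 (SE 0.80, adjusted p = 0.105) and passed in 2 of 15 alternatives. Without control replicate 3, ccnd1.L read -1.01 and hmgn3.L 3.14, and both passed. The list did not pass with PTU or MMI at 96 h, with adjusted p of 0.415 and 0.391, and ribosome genes with PTU gave 0.415.

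In the hindlimb at 24 h the inhibitors gave 0 calls among 43 pairs for PTU, 40 for MMI and 47 for PER, with 0, 1 and 3 at an unadjusted p under 0.05. With PTU, ccnd2.L read 0.42 (SE 0.21), ccnd1.L -0.52 (SE 0.29) and gapdh.S -0.36 (SE 0.22), where its other pairs read 0.22 and 0.11. Without PTU replicate 1 ccnd1.L read -0.06 and gapdh.S -0.05, and with bright centring ccnd2.L read 0.24. At its other end ccnd1.L reached -0.86, and it passed in 0 of 15 alternatives. With MMI, the calcium-binding calb1.L read -0.71 (SE 0.36), hmgn3.L 1.55 (SE 0.80) and rest.S 0.83 (SE 0.44). There calb1.L fell to -0.21 with the deposited values, hmgn3.L to 0.56 with array weights and rest.S to 0.38 without control replicate 1. With PER, rest.S read -1.33 (SE 0.44, adjusted p = 0.122), pabpc1.S -1.35 (SE 0.74; above background on 0 of 3 arrays with PER) and mcm3.L 0.97 (SE 0.57). Without control replicate 1, rest.S read -1.78 and passed, while mcm3.L read 0.49. With the floor pabpc1.S read -0.84. No list passed.

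In the tail at 48 h, PTU, MMI and PER gave 0 calls among 48, 51 and 48 pairs, with 3, 16 and 1 at an unadjusted p under 0.05. With MMI the 5 pairs of rpl8.S read between -0.67 and -0.56, gapdh.S -0.88 (SE 0.31, adjusted p = 0.123), with its other pairs at -0.83 and -0.86, and the haemoglobin gene hbd.S -1.02 (SE 0.41, adjusted p = 0.147). The ribosome list, which here is rpl8.S alone, passed with an adjusted p of 0.0158, but not with an estimated correlation (adjusted p = 0.168), with only these groups (adjusted p = 0.0524) or with the deposited values (adjusted p = 0.491), and it passed in 7 of 9 alternatives. 5 of its pairs passed when adjusted over the list alone. With the deposited values as they stand the median pair was higher with MMI by 0.89, against -0.31 after normalization, and rpl8.S, gapdh.S and hbd.S read 0.30, 0.17 and 0.03, the opposite direction. With array weights rpl8.S passed (adjusted p = 0.0476).

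With PER in the tail, the energy list shifted downwards (adjusted p = 0.00509, and an adjusted p of 0.00645 with an estimated correlation), although none of its 6 pairs passed alone or when adjusted over the list alone. Of the 6, 3 were pairs for gapdh.S, at -0.66 (SE 0.39), -0.46 and -0.37. The others were pkm.S at -0.88 (SE 0.81; lower than the control mean in 1 of 3 animals), aldoc.L at -0.58 (SE 0.66) and ldhb.S at -0.05 (SE 0.25). pcna.S read 1.12 (SE 0.43, adjusted p = 0.808) and thdl18.S 0.83 (SE 0.67). With the deposited values gapdh.S read -0.30, and with the floor thdl18.S read 1.44. With PTU, tpm4.S read -1.29 (SE 0.65), thdl18.S 1.14 (SE 0.67) and gapdh.S -0.60 (SE 0.39), and the energy list had an adjusted p of 0.129. There pkm.S read -0.88 and aldoc.L -0.67. PER and PTU share the same controls, so the shift of the list cannot be tied to PER alone. Without PTU replicate 3 tpm4.S read -0.19, and with the deposited values gapdh.S read -0.11.

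PTU and MMI are both thionamides, given here at 20 and 100 mg/L. Set directly against each other they gave 0 calls among 41 pairs in hindlimb at 24 h, 47 at 96 h and 52 in tail, with 3, 3 and 5 at an unadjusted p under 0.05. The median half-widths of the 95% intervals were 0.89, 0.89 and 0.87 on the log2 scale. At 24 h ccnd1.L read -0.97 (SE 0.29, adjusted p = 0.0938), mamdc2.L 1.09 (SE 0.47) and ldhb.S -0.42 (SE 0.19), and 1 cell cycle pair, ccnd1.L, passed when adjusted over the list alone. ccnd1.L read -1.31 without PTU replicate 3, and -1.23 without MMI replicate 2, where mamdc2.L read 1.67; these values passed, as did ccnd1.L with bright centring (-1.46). ccnd1.L read -0.51 without PTU replicate 1, mamdc2.L 0.19 without MMI replicate 3, and ldhb.S -0.06 with median centring. At 96 h des.1.S read 1.36 (SE 0.56), pou2f1.S 0.84 (SE 0.53) and tuba1 0.76 (SE 0.58), with des.1.S and pou2f1.S above background on no MMI array. That may reflect the noise of the arrays in part. At that time rpl35a.S averaged 11.35 with PTU and 11.85 with MMI, yet was above background on 3 of 3 and 0 of 3 arrays. There des.1.S read 2.11 without MMI replicate 1, 1.97 with median centring and 1.95 with bright centring, which passed, and 0.84 without MMI replicate 2. pou2f1.S read 0.42 with the deposited values and tuba1 0.14 without MMI replicate 3. In tail rpl8.S read 0.61 (SE 0.22), hbd.S 1.00 (SE 0.41) and tpm4.S -1.33 (SE 0.65). The ribosome list passed there with an adjusted p of 0.012, but not with an estimated correlation (adjusted p = 0.171) or with the deposited values (adjusted p = 0.0535), where rpl8.S read -0.06, hbd.S 0.24 and tpm4.S -2.24. Without PTU replicate 3 tpm4.S read -0.23.

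Changes with 2 inhibitors that share controls correlate by chance. At 96 h the correlations across pairs were 0.862 for PTU and MMI, 0.754 for PTU and PER and 0.71 for MMI and PER. Unchanged groups against shared controls gave means of 0.478, 0.495 and 0.477. The covariances were 0.699, 0.424 and 0.503, against simulated ones of 0.145, 0.158 and 0.149. Pair 260 was called in all 3 comparisons. The value for PTU and MMI lay above the range of 95% of the simulations (-0.120 to 0.828), and the others lay inside theirs. All 3 correlations share the dim control replicate 2, without which the calls ended, and they were not rerun without it. The simulations drew on all hindlimb arrays, so the excess cannot be separated from that control. With 3 controls no split into groups of at least 2 was possible. At 24 h and in tail the 6 correlations ran from 0.246 to 0.52, within the simulated range.

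The effects at 96 h minus those at 24 h gave 0 calls for PTU among 65 pairs, for MMI among 48 and for PER among 62, with 8, 4 and 13 at an unadjusted p under 0.05. The time points were scaled separately by the authors. With PTU, pou2f1.S read 2.00 (SE 0.67, adjusted p = 0.18), ccnd2.L -0.79 (SE 0.30) and tuba1 1.70 (SE 0.82). With MMI, nkx2-2.S read 1.65 (SE 0.59), calb1.L 1.01 (SE 0.51) and ldhb.S -0.52 (SE 0.26). With PER, pabpc1.S read 2.98 (SE 1.04), rest.S 1.58 (SE 0.62) and ccnd1.L -1.01 (SE 0.41), and 1 ribosome pair, pabpc1.S, passed when adjusted over the list alone. Without 96 h control replicate 3, nkx2-2.S read 2.38 and pabpc1.S 3.87, and both passed; without 96 h control replicate 2 nkx2-2.S read 0.90. With bright centring ldhb.S read -1.70 and passed (adjusted p = 0.00763), the only pass in its 21 alternatives (adjusted p up to 0.623), and calb1.L read 0.51. With a floor in place of normexp pou2f1.S read 0.62 and pabpc1.S 1.92. pou2f1.S passed in 2 of 17 alternatives (adjusted p from 0.00972 to 0.732). With median centring ccnd1.L read 0.15 and ccnd2.L -0.38.

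Hindlimb controls at 96 h differed from those at 24 h in 8 of 40 pairs, 2 higher and 6 lower. This balance depends on the scaling: with the deposited values as they stand most calls were higher. mt4.L was at least 5.27-fold lower (adjusted p = 0.00052) and rest.S at least 1.88-fold lower (adjusted p = 0.00263). The call for rest.S ended with only these groups (adjusted p = 0.061) and with the deposited values (adjusted p = 0.121). nkx2-2.S was lower by a log2 change of -1.49 (SE 0.41), and ywhab.L, a 14-3-3 protein gene, higher by 1.86 (SE 0.52), passing in 11 and 10 of 15 alternatives. nkx2-2.S read -0.73 with 96 h control replicate 2 left out (adjusted p = 0.158) and -1.46 without 24 h control replicate 1 (adjusted p = 0.0611), where ywhab.L read 1.23 (adjusted p = 0.241). The call for ywhab.L also ended with median centring (0.96, adjusted p = 0.287), bright centring (1.35, adjusted p = 0.0885), only these groups (adjusted p = 0.07) and the deposited values (adjusted p = 0.0807), and that for nkx2-2.S with only these groups (adjusted p = 0.236) and the deposited values (-1.06, adjusted p = 0.137). mt4.L passed in 12 of 12 alternatives, but pairs below background at 96 h cannot be tested with a 24 h control left out. The 2 largest changes were gapdh.S pairs, at least 8.84-fold and 9.69-fold lower, while the third pair for the same gene read 0.05. The energy list passed (adjusted p = 0.000279, and an adjusted p of 0.000459 with an estimated correlation) through those pairs: 2 of its 4 pairs were called, and the remaining gene, ldhb.S, read 0.40 (SE 0.19). As the sets were scaled separately, time and set cannot be told apart.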

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

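Signal over background limits which pairs can be tested. Values at or below 0 were also floored in place of normexp, arrays also centred on bright probes, doubtful arrays left out, and the gapdh pairs left out of the controls at 96 h against 24 h; these alternatives were chosen after seeing the data. Leaving out the gapdh pairs alone changed no call of that comparison's named genes. Leaving out dim probes changed no number of calls by over 1.5 times. The causes of the changes below were not tested, except that fewer samples weaken a test.

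For T3 in tail (0 calls), 2 were called with only the groups compared and 2 with the floor, all higher, 6 with array weights (4 higher, 2 lower) and 2, both lower, by the submitters' rule, which has no test. For PTU, MMI and PER at 96 h (4, 2 and 1) the numbers were 1, 0 and 0 with only the groups compared, 0, 0 and 0 with the deposited values, with weights and without the doubtful control, and 7, 4 and 9 with median centring, of which 6, 3 and 8 were higher. Bright centring gave 5 for MMI (3 higher, 2 lower) and 3 for PER (1 higher, 2 lower), and the floor 0 for PER. The submitters' rule gave 3 for PTU, all lower, where the 4 calls were higher, 4 for MMI, all higher, and 5 for PER (3 higher, 2 lower). Elsewhere it gave 3 higher for T4 in hindlimb, 1 lower for T4 in tail, 1 lower for PTU and 2 higher for MMI in hindlimb at 24 h, and 3, 14 and 1 for PTU, MMI and PER in tail, all higher, although the genes named with MMI in tail read lower. The floor gave 1 for PTU and weights 1 for MMI in tail.

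For the difference of T3 and T4 effects (0), hindlimb gave 1 with median centring, 2 with complete probes, 3 with weights and 2 with the floor; tail gave 1 with weights, 2 with the floor and 1 without the doubtful control. For PTU against MMI (0), bright centring gave 1 at 24 h, and at 96 h 1 was called with only the groups compared, 3 with median centring, 1 with weights and 3 with bright centring. For the effects at 96 h minus 24 h (0), PTU gave 1 with only the groups compared and MMI 1 with bright centring, ldhb.S. Controls at 96 h against 24 h (8; 2 higher, 6 lower) gave 5 with only the groups compared and 15 with the deposited values (11 higher, 4 lower). Tail against hindlimb (31; 18 higher, 13 lower) gave 48 with bright centring (38 higher, 10 lower). The correlation of T3 and T4 changes in hindlimb, 0.12, was -0.575 over complete probes, fewer than in the main comparison; the other correlations moved by less than their simulated spread. The number of lists passing, 6, stayed within 1.5 times under the alternatives run for it.

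With 1 array left out, calls ranged from 0 to 2 for T4 in hindlimb and in tail, for MMI in hindlimb at 24 h, for the T3 and T4 difference in hindlimb, for PTU against MMI in hindlimb at both times, and for the PTU and MMI effects at 96 h minus 24 h. They ranged from 0 to 1 for T3 in tail, PER in hindlimb at 24 h and the hormone difference in tail, and from 0 to 6 for the PER difference between times. At 96 h they ranged from 0 to 9 for PTU, 0 to 3 for MMI and 0 to 5 for PER; control replicate 3 left out gave the 9 and the 5, control replicate 2, or any array of the inhibitor, the 0, and MMI gave 1 without control replicate 1. A pair above background on 3 arrays only is no longer tested once 1 of them is left out. Controls at 96 h against 24 h ranged from 1 to 10, with 1, 3 and 4 without 24 h control replicate 1, 2 and 3, for that reason in part.

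Scaling moved the median change of all tested pairs: for PER at 96 h from 0.22 to 0.83 with median centring, for MMI in tail from -0.31 to 0.89 with the deposited values, and for tail against hindlimb from 0.03 to 0.72 with bright centring. Directions turned for rpl8.S (0.30), gapdh.S (0.17) and hbd.S (0.0255) with MMI in tail and for rpl8.S (-0.0612) in PTU against MMI with the deposited values, and for ccnd1.L (0.17) and ccnd2.L (0.0124) with PER at 96 h and ccnd1.L (0.15) in its difference between times with median centring.

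Animals of different groups share only a replicate number: deviations of same-numbered arrays correlated between -0.479 and 0.488. With the replicate number as a block, 1 pair was called for T4 in hindlimb, 1 for T3 in tail, 2, 0 and 0 for PTU, MMI and PER at 96 h, and 1 for the PTU effect at 96 h minus 24 h. The block could not be fitted for controls at 96 h against 24 h or tail against hindlimb, since each block lies within 1 tissue and time.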

Other observations

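The tests of gapdh, of the calls at 96 h, of the tail control and of the tubulin genes were chosen after these results, or values close to them, were seen. The counts over other splits of the samples were planned before. In the 14 groups of 4 values examined for a sample far from the others, 0 stood out, where chance gives about 0.7.

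2 gapdh.S pairs were below background in the hindlimb at 96 h. They were above background on 26 of 26 arrays at 24 h and on 0 of 12 at 96 h, treated animals included, while the remaining pair stayed above on 12 of 12 (median 32.1 noise SD). A fall of gapdh mRNA is argued against by that pair, whose log2 change in controls was 0.0496 (95% interval -0.59 to 0.69). The spots of these pairs may have carried no target or been tabulated differently in this set. That remains a candidate explanation, since 0 of 12 arrays showed either pair. Pair 393 had a like pattern: it was above background on 3 of 3 controls at 24 h and on 0 of 2 measured at 96 h.

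The calls at 96 h in hindlimb fall into parts. For pair 260 and nkx2-2.S, the 4 calls had a median log2 change of 1.49, which fell to 0.63 without control replicate 2, so that 1 dim control array may account for them. For the 3 pairs called with PTU that no control showed above background, pou2f1.S, tuba1 and pair 88, the median was 1.64 with that array and 1.55 without it, and 1.46 or 2.02 under the other scalings. These are differences from background, and pou2f1.S read 0.62 with a floor in place of normexp. They thus decide nothing about that array or the scaling, and an effect of PTU stays open too. Being above background is also not comparable between these groups. For rpl8.S (pair 34), at means of 11.2 with PTU and 11.3 in controls, 3 of 3 and 1 of 3 arrays were above it. For pair 260 and nkx2-2.S the median did not fall with the deposited values or median centring (1.53 or 1.68). The median of all tested pairs moved there too. It went from 0.03 to 0.42 and 0.27 with MMI, and from 0.22 to 0.54 and 0.83 with PER. With PTU it went from 0.21 to -0.03 and 0.53. The part of quantile normalization in these calls thus stays open.

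Replicate 3 of the tail controls for T4 stood apart, with r = 0.491 to the median of its set. Low sensitivity is argued against: 11 of 24 pairs brighter than 10 noise SD on the other arrays of the set were below background there, among them des.1.S, pkm.S, thdl18.S and mt4.L. A hindlimb sample under a tail label is argued against by the 13 pairs lower in tail, whose median of 9.87 lies below the 12.3 to 13.4 of hindlimb controls. That array was itself among the tail controls that chose these pairs, so this test is not independent of its label. Of these genes, ccnd2.L and gapdh.S were called in 26 of 26 alternatives. They read 9.84 and 11.87 on that array, against hindlimb means of 13.53 and 14.14. The correlation alone decided nothing: it was lower by -0.0631 with hindlimb than with tail, within its bootstrap SD of 0.173. Other explanations were not tested.

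A rise of tuba1, tubb4b.L and cct3.S with T3 in tail that the spread between arrays hides is a hypothesis that these data cannot test, since the genes were picked by their p in the same comparison. With array weights 3 of 3 passed, at log2 changes of 1.68, 1.35 and 1.65 and adjusted p of 0.00543, 0.0457 and 0.0342. The estimate of the weights stopped before it converged. No control was above background for these genes, a state that is not comparable between these groups. Over all alternatives tuba1, tubb4b.L and cct3.S passed in 4 of 12, 2 of 16 and 3 of 11, with adjusted p from 0.00348 to 0.445, 0.0394 to 0.81 and 0.00348 to 0.701.

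Other splits of the samples were counted for each number of calls. For tail against hindlimb controls, 1 of 100 splits, the real one, gave as many as its 31 calls, and the highest other gave 5. A chance division of these arrays can thus be excluded. No set of arrays holds both tissues, so differences between sets are not excluded by these splits. The comparisons of 3 against 3 make 10 splits, too few for a share under 0.05. There PTU, MMI and PER at 96 h gave 4, 2 and 1 calls against 2, 3 and 11 in the highest other split, reached by 1, 3 and 3 splits, and controls at 96 h against 24 h gave 8 against 1. A split with 11 calls points to a structure of the samples, whose source was not tested. Where the real split gave 0 calls, every split gives as many by construction, so the count decides nothing. The highest other splits there gave 0 to 3 calls in the comparisons of 3 against 3 (10 of 10 splits), up to 2 in the 4 hormone comparisons (35 of 35) and up to 15 in the differences of effects (100 of 100), where the splits mix time points or hormones.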
